A study of Homo sapiens with 9 samples.

How the data were processed

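RNA sequencing was analysed for 9 libraries of the human lung adenocarcinoma line PC9/GR, with 3 libraries in each of the groups labelled shNC, sh1-HUMT and sh2-HUMT. Some sample titles spell the target HUNT, and the design text of the series describes a different study (the RNA SNHG1 in a retinoblastoma line), so groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, cells grew in medium with fetal bovine serum, RNA was extracted with Trizol, and libraries followed the BGI500 protocol, with the same text for every sample.

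The authors deposited 1 table of 27059 genes, whose estimated counts per gene and library carry 2 decimals. Of its genes, 91.3% held at least 1 value that was not whole (tolerance 0.005). The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 without saying which step each served, and the genome build is not given in the sources used here. Per the file headers, the columns belong to A549 cells with NC, Si_1 and Si_2 and replicate numbers, whereas the labels name PC9/GR and shRNA. Each count column was matched to the title of the same arm and replicate number, so every comparison rests on that match. A further 15 value columns, 9 of expression values and 6 of group averages, were not used. Counting is not stated to use strand, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes can be split between them by the estimation.

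Library totals ran from about 21891100 to 22159900 estimated counts. Of the genes listed, 23296 have an Entrez gene ID and 3763 have only a provider identifier, of which 1195 were tested; 117 were at 0 in every library. The most abundant entry, known only by a provider identifier, took 8.70 to 10.7% of counts. HUMT was matched through the synonym column of a RefSeq gene table of assembly GRCh38.p14 to LINC00857 (gene ID 439990). No coordinates are given, because the authors' build is unknown.

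Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM normalization (factors 0.968 to 1.02), filterByExpr by group, which kept 18540 genes, and the robust quasi-likelihood test with all 9 libraries in 1 fit of 3 group means. Adjusted p-values are Benjamini-Hochberg values from that fit, with a threshold of 0.05 and no minimum fold. CPM used TMM-scaled library sizes, standard errors are on the log2 scale, and intervals are at 95%. The common biological coefficient of variation was 7.02%. Comparisons were each hairpin group against shNC, the genes changed the same way in both, and sh2-HUMT against sh1-HUMT. A fold minimum of 1 on the log2 scale was an alternative. Lists were tested with camera (preset correlation 0.01, log2 CPM with a prior count of 2) from limma 3.58.1, adjusted over the lists, with the correlation estimated per list as an alternative and fry beside it. Of 30 lists, 29 had at least 3 tested genes; the list of mitochondrially encoded genes was not analysed here. Of 634 list entries, 587 matched by symbol and 5 by gene ID, 24 were not matched, and the rest repeated a gene under another symbol.

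The design, the lists, the rule for naming genes and the other settings to try were set before the data were examined. Named genes came from 5 parts of the rule, and all parts but the last needed a mean of at least 5 CPM. The first took the 12 highest and 12 lowest genes called in both comparisons with all 6 libraries beyond all 3 controls, ranked by the smaller change. The next took the 6 highest and 6 lowest called genes with non-overlapping libraries of each comparison against shNC, and another the same numbers for sh2-HUMT against sh1-HUMT. A further part took up to 4 called members of each list with the smallest adjusted p, and the last a fixed set of 17 genes (HUMT, FOXK1, EGFR, MET, AXL, ERBB3, HK2, LDHA, PKM, SLC2A1, PFKFB3, CDKN1A, MKI67, CDH1, VIM, ABCB1 and IFIT1). Some genes that the rule took are not reported here. By chance, 10% of genes have non-overlapping groups when 3 libraries are set against 3.

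Those other settings were DESeq2 1.42.0 (Wald test), its size factors in edgeR, upper-quartile normalization, no filter on low counts, a mean count of at least 10, the replicate number as a block, only the 2 groups compared, the fold minimum, the estimated correlation, and leaving out each library in turn. After the data were seen, a correction for GC content and transcript length (a spline per library, used as an offset), the removal of the 2 most abundant entries and the test of lists between the hairpin groups were added. The steps were tested on simulated counts over 18250 genes. For sh1-HUMT against shNC, 26.0% of genes changed 1.2-fold, 57.4% of those changed 1.5-fold, 66.0% at 2-fold and 97.9% at 4-fold were recovered, with 14 false calls; for sh2-HUMT the shares were 20.0%, 61.7%, 66.0% and 97.9%, with 6. The simulated counts gave 132 and 123 calls in all, far fewer than the real data. The adjusted threshold was therefore stricter there, and these shares may not carry over to the real comparisons. Changes near 1.2-fold in genes not called may still have been missed. In libraries of a group the variance was 1.65 to 2.69 times sampling noise, so no pair of libraries agreed within sampling noise.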

Results

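Gene expression was measured by RNA sequencing in 9 libraries of PC9/GR, a lung adenocarcinoma cell line made resistant to gefitinib, an inhibitor of the EGF receptor. The labels name 3 groups of 3 libraries: cells with a control hairpin (shNC) and cells with either of a pair of short hairpin RNAs designed against the long noncoding RNA HUMT (sh1-HUMT and sh2-HUMT). The series title ties HUMT to chemoresistance and glycolysis, so the comparisons ask what the hairpins changed, glycolysis genes included. The column headers of the deposited table name A549, another lung adenocarcinoma line, and "Si" in place of "sh", so the identity of the cells rests on the labels alone. Library totals ran from about 21891100 to 22159900 estimated counts, and counts varied between libraries of a group by 7.02% (biological coefficient of variation). Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are CPM, counts scaled to the size of each library, as mean ± SD with n = 3. Where a pair of values follows a gene or list, the first is for the libraries labelled sh1-HUMT and the other for those labelled sh2-HUMT, each against shNC.

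The counted gene for HUMT did not pass the test in either group labelled as a knockdown. It was LINC00857 (gene ID 439990), for which HUMT is a listed synonym, and stood at 9.36, 9.85 and 8.51 CPM in the shNC libraries, at 9.17, 9.58 and 10.1 CPM in those labelled sh1-HUMT, and at 8.75, 9.60 and 8.50 CPM in those labelled sh2-HUMT. Group levels were 9.24 ± 0.679, 9.61 ± 0.465 and 8.95 ± 0.575 CPM. The log2 fold change was 0.06 (95% interval -0.14 to 0.25, adjusted p = 0.685) for libraries labelled sh1-HUMT and -0.05 (95% interval -0.24 to 0.15, adjusted p = 0.740) for libraries labelled sh2-HUMT. The sh2-HUMT value was 0.01 without shNC replicate 2 and 0.02 after a correction for GC content and transcript length. Between the groups labelled sh2-HUMT and sh1-HUMT it was -0.10 (adjusted p = 0.708). With 181 to 226 counts per library, the lower bounds correspond to levels at 0.909 and 0.845 of the control, so depth was not what hid a loss of 50%. Reads of genes overlapping LINC00857 on either strand could not be told apart, since no source states strand-aware counting. Because no loss of the target was found, every direction given here is a difference between libraries as labelled, not an effect of a measured loss of HUMT.

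**Figure D1:**
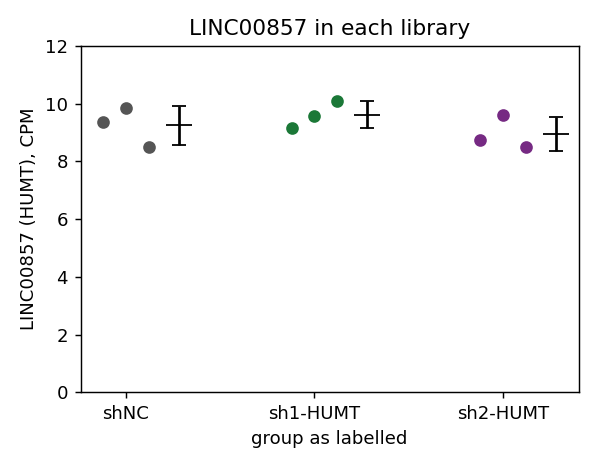
LINC00857 (HUMT) in CPM for each of the 9 libraries by labelled group, with the group mean and SD drawn beside the points. All libraries lie between 8.50 and 10.1 CPM, and the 3 groups overlap.

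In the libraries labelled sh1-HUMT, stress-induced genes were far below control. HSPA6, an inducible member of the HSP70 chaperones, stood at 0.388 ± 0.214 CPM against 197 ± 4.49 CPM in shNC (n = 3 each), and EGR1, a transcription factor induced within minutes by growth factors and stress, at 6.20 ± 0.318 against 326 ± 5.83 CPM. The AP-1 subunits FOS and JUN were 15.5-fold and 9.04-fold lower, and DNAJB1, an HSP40 co-chaperone, 8.02-fold lower. MUC1, a membrane mucin, rose from 18.7 ± 0.773 to 50.6 ± 1.44 CPM, and GFRA1, a receptor for the growth factor GDNF, from 2.90 ± 0.343 to 9.61 ± 0.242 CPM. Of 18540 genes tested with edgeR, 5923 differed from shNC, 2902 higher and 3021 lower. Most changes were small: the median called gene differed 1.22-fold, and 361 genes (155 higher and 206 lower) differed at least 2-fold.

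In the libraries labelled sh2-HUMT, those genes moved in the same directions. HSPA6 stood at 0.331 ± 0.224 CPM and EGR1 at 4.94 ± 0.22 CPM, while FOS, JUN and DNAJB1 were 15.6-fold, 11.2-fold and 7.47-fold lower. MUC1 rose to 56.0 ± 3.13 CPM and GFRA1 to 9.59 ± 0.429 CPM. In edgeR, 6019 of 18540 genes differed from shNC, 2956 higher and 3063 lower, with a median of 1.23-fold among called genes. Of these, 372 differed at least 2-fold, 179 higher and 193 lower.

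In both groups labelled as knockdowns, 4654 genes differed from shNC the same way, 2276 higher and 2378 lower, which is 78.6% of the sh1-HUMT calls and 77.3% of the sh2-HUMT calls. The balance between higher and lower calls turned with upper-quartile normalization, to 3276 higher and 2691 lower for sh1-HUMT, 3255 and 2731 for sh2-HUMT and 2572 and 2100 for both. It also turned in all 3 counts without the 2 most abundant entries (2980 and 2957, 3043 and 2975, 2354 and 2309), without shNC replicate 1 (2492 and 2380, 2570 and 2453, 1977 and 1867) and without shNC replicate 3 (2542 and 2541, 2577 and 2507, 1990 and 1942). Among the genes lowest in both were FOSB (-4.55 and -4.54, log2), HSPA1A (-4.27 and -3.90), ATF3, a stress-induced transcription factor (-3.79 and -4.02), PPP1R15A, the phosphatase subunit that reverses phosphorylation of eIF2alpha (-2.67 and -2.86), and ZFAND2A (-2.26 and -2.40). EGR2 fell from 383 to 402 counts per control library to 1 to 4 counts in the other 6. HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain. The genes highest in both included GFRA1 (1.73 and 1.73), the receptor GPR132 (1.67 and 1.66), TM4SF20 (1.48 and 1.49) and the mucins MUC16 (1.48 and 1.70), MUC1 (1.43 and 1.58) and MUC2 (1.22 and 1.55). C10orf91, LNCOC1, NEB, C9orf152 and LRRC32 also rose, by 1.15 to 1.39 on the log2 scale. RLBP1, a retinoid-binding protein, was higher too (1.31 and 1.38, adjusted p = 0.0285 and 0.0226). Its sh1-HUMT call was lost without shNC replicate 1 (adjusted p = 0.0685) or 2 (0.0932), sh1-HUMT replicate 1 (0.0584) or 3 (0.0799) or sh2-HUMT replicate 3 (0.0505), with no filter on low counts (0.0519) and with only the 2 groups compared (0.0702; range over alternatives 0.00245 to 0.0932). Its sh2-HUMT call was lost without shNC replicate 1 (0.0543) or 2 (0.0774) or sh2-HUMT replicate 1 (0.0688) or 3 (0.0589; range 0.00119 to 0.0774). KIFC2, a kinesin, was the 1 gene called in opposite directions (-0.13 and 0.17). Its sh1-HUMT call was lost without shNC replicate 1 (adjusted p = 0.0799) or 2 (0.0590) or sh1-HUMT replicate 2 (0.0525) or 3 (0.0750; range 0.00526 to 0.0799), and its sh2-HUMT call after a correction for GC content and transcript length (log2 0.03, adjusted p = 0.593; range 5.1e-04 to 0.593).

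Both comparisons share their controls, which alone gives some overlap. In 20 simulations of unchanged groups against shared controls, 0.15 genes on average and at most 1 were called in both, and independent lists of these sizes would share 463 higher and 499 lower genes. Across genes, which are not independent replicates, the fold changes of both comparisons had Pearson r = 0.738 (simulated mean 0.499) and a covariance of 0.187 (simulated 0.0541, a difference of 0.133). The same sign was found in 83.3% of genes against 66.9% in the simulations. The simulations held no difference between the control cultures and the others, so they do not bear on a shift that the controls share. With 3 control libraries the controls could not be split, so part or all of the excess may come from the shared controls. The first principal component, 27.6% of the variance, placed the 3 controls at -39.4 to -37.5 and the other 6 libraries at 17.3 to 21.5.

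**Figure D2:**
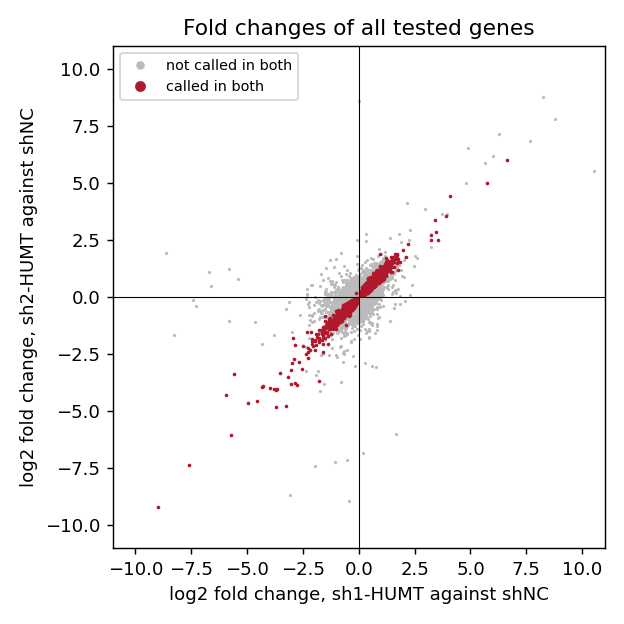
Log2 fold change of each of 18540 tested genes for libraries labelled sh1-HUMT against shNC (x axis) and sh2-HUMT against shNC (y axis), with genes called in both in red. The 4654 genes called the same way in both have the same sign on both axes. Over all 18540 tested genes, called or not, Pearson r = 0.738.

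**Figure D3:**
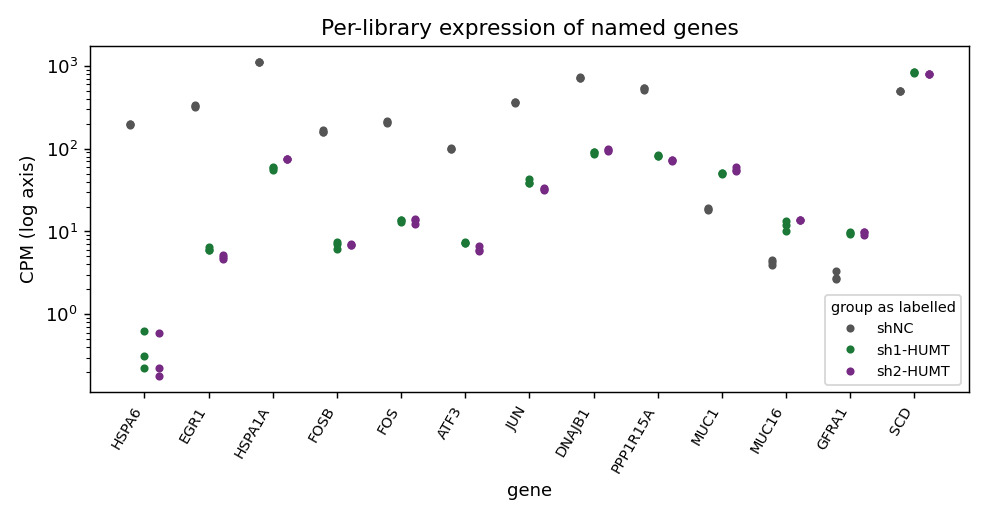
CPM of 13 named genes in each library on a log axis, coloured by labelled group. The 3 shNC libraries lie above the other 6 for HSPA6, EGR1, HSPA1A, FOSB, FOS, ATF3, JUN, DNAJB1 and PPP1R15A, and below them for MUC1, MUC16, GFRA1 and SCD.

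Genes of protein folding and stress responses fell as groups. All 12 heat shock proteins tested fell in both labelled groups (12 of 12 also adjusted over the list alone), with a median log2 change of -1.07 and -0.99; HSPH1, an HSP110 chaperone, fell from 282 ± 9.82 CPM to 90.5 ± 2.94 and 95.3 ± 2.12 CPM. Of 20 genes of the response to the transcription factor ATF4, 18 fell in both comparisons (19 changed adjusted over the list alone, 18 of them lower), with medians of -0.58 and -0.75. Examples are TRIB3, a pseudokinase (-1.13 and -1.37), STC2, a secreted glycoprotein (-0.77 and -0.97), and GARS, the glycyl-tRNA synthetase (-0.64 and -0.88). Of 17 genes of the unfolded protein response of the endoplasmic reticulum, 16 fell in both comparisons (16 and 17 adjusted over the list alone). HERPUD1, a factor in degradation of misfolded proteins, fell from 179 ± 5.41 CPM to 62.7 ± 0.503 and 60.8 ± 1.90 CPM, and HSPA5, the main HSP70 of the endoplasmic reticulum, changed by -1.09 and -1.13. MANF (-0.88 and -0.68) and PDIA4 (-0.36 and -0.34) fell with them. The list test camera, which asks whether a list moves against all other genes, gave adjusted p = 4.4e-18 and 1.3e-17 for heat shock, 2.2e-17 and 5.1e-20 for ATF4 and 1.0e-13 and 6.9e-15 for the unfolded protein response. These calls held with an estimated correlation, at adjusted p = 0.00722 and 0.00763 for each of the 3 lists.

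Most genes of fatty acid synthesis rose, and among cholesterol synthesis and airway genes more rose than fell. Of 11 genes of fatty acid synthesis, 9 rose in both comparisons and 1 fell in the sh1-HUMT comparison (11 changed adjusted over the list alone in each). SCD, the stearoyl-CoA desaturase, rose from 498 ± 1.62 CPM to 831 ± 12 and 796 ± 6.76 CPM, the desaturases FADS1 and FADS2 by 0.40 and 0.37 and by 0.64 and 0.55, and SREBF1, a regulator of lipid synthesis, by 0.46 and 0.45 (log2). Of 20 genes of cholesterol synthesis, 9 rose and 2 fell in libraries labelled sh1-HUMT and 12 rose and 1 fell in libraries labelled sh2-HUMT (14 changed adjusted over the list alone in each). INSIG1, which restrains sterol synthesis, rose from 17.1 ± 0.558 CPM to 21.7 ± 0.466 and 24.7 ± 0.924 CPM. Of 14 alveolar and airway lineage genes, 8 rose in each comparison (9 and 8 adjusted over the list alone). MUC5AC, a secreted airway mucin, rose from 1828 ± 131 CPM to 3287 ± 295 and 3601 ± 63.5 CPM, beside MUC5B (0.79 and 0.88) and FOXA1, a lineage transcription factor (0.60 and 0.67). Camera gave adjusted p = 4.4e-08 and 1.1e-07 for fatty acid synthesis, 3.0e-04 and 3.9e-05 for cholesterol and 2.6e-04 and 1.8e-04 for the lineage genes. With an estimated correlation, fatty acid synthesis (adjusted p = 0.00722 and 0.00763) and lineage genes (adjusted p = 0.0415 and 0.0386) held. Cholesterol synthesis held for libraries labelled sh2-HUMT (adjusted p = 0.0441 with an estimated correlation) and was lost for libraries labelled sh1-HUMT (adjusted p = 0.0754 with an estimated correlation).

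Most glycolysis genes fell slightly. Of 24 tested, 17 fell and 1 rose in each comparison (19 changed adjusted over the list alone), with median log2 changes of -0.15 and -0.15. PDK1, a kinase that inhibits pyruvate dehydrogenase, fell from 30.3 ± 1.38 CPM to 15.8 ± 0.299 and 15.5 ± 1.04 CPM. The glucose transporters SLC2A1 (-0.45 and -0.39) and SLC2A3 (-0.39 and -0.27), the lactate transporter SLC16A1 (-0.53 and -0.72), hexokinase HK2 (-0.55 and -0.47) and PFKFB3 (-0.25 and -0.23) also fell. Pyruvate kinase PKM did not pass the test (0.03 and 0.02, adjusted p = 0.509 and 0.583). The list was called by camera at adjusted p = 7.6e-07 and 5.7e-06, and the calls were lost at adjusted p = 0.118 and 0.113 with an estimated correlation; fry, which asks whether genes of a list move on balance one way, gave adjusted p = 1.6e-05 and 2.5e-05. Lactate dehydrogenase LDHA changed by -0.10 and -0.09 (adjusted p = 0.0103 and 0.0185). Its sh1-HUMT call was lost without shNC replicate 1 (adjusted p = 0.0559) or 3 (0.0503), and with a correction for GC content and transcript length (log2 -0.03, adjusted p = 0.328; range over alternatives 4.6e-04 to 0.328). Its sh2-HUMT call was lost without shNC replicate 1 (0.0964) or 3 (0.0888), without sh2-HUMT replicate 1 (0.0604), 2 (0.0682) or 3 (0.0592), and with that correction (log2 -0.0027, adjusted p = 0.947; range 0.00223 to 0.947).

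Other metabolic lists moved less evenly. Of 18 hypoxia response genes, 8 fell and 4 rose in libraries labelled sh1-HUMT, and 7 fell and 5 rose in libraries labelled sh2-HUMT (15 changed adjusted over the list alone in each). ADM, the hormone adrenomedullin, fell from 184 ± 1.72 CPM to 80.5 ± 1.99 and 82.5 ± 0.678 CPM, beside VEGFA (-0.54 and -0.47), DDIT4 (-0.49 and -0.51) and P4HA1 (-0.35 and -0.37). The hypoxia list was called for libraries labelled sh1-HUMT (adjusted p = 0.0206; adjusted p = 0.202 with an estimated correlation) and not for libraries labelled sh2-HUMT (adjusted p = 0.0572), where it was called without shNC replicate 1 (adjusted p = 0.0392) or without sh2-HUMT replicate 3 (0.0332; range over alternatives 0.0332 to 0.292). Of 20 NRF2 target and pentose phosphate genes, 8 fell in each comparison and 5 and 6 rose (13 and 14 changed adjusted over the list alone), and the list was not called (adjusted p = 0.262 and 0.312). HMOX1, a heme oxygenase, fell by 1.24 and 1.32, OSGIN1 and SRXN1 changed by -0.82 and -0.92 and by -0.41 and -0.49, and UGDH rose by 0.34 and 0.23 (log2). Of 18 genes of the tricarboxylic acid cycle, 4 fell in each comparison and 1 and 2 rose (4 and 6 adjusted over the list alone), with MDH2 at -0.15 and -0.17 (-0.09 for sh1-HUMT after the GC and length correction); the list was not called (adjusted p = 0.667 and 0.592).

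Most cytosolic ribosomal protein genes, and part of the respiratory chain genes, fell by small amounts. All but 2 of 34 cytosolic ribosomal protein genes fell in libraries labelled sh1-HUMT and 26 in libraries labelled sh2-HUMT (32 and 31 adjusted over the list alone), with medians of -0.21 and -0.18. RPL7A stood at 1118 ± 37.1 CPM in shNC and at 931 ± 41.1 and 969 ± 3.61 CPM, and RPS14 and RPL10A changed by -0.36 and -0.30 and by -0.29 and -0.28. Ribosomal protein genes have many processed pseudogenes, so their reads may be shared. Of 37 nuclear genes of oxidative phosphorylation, 23 fell and 1 rose in libraries labelled sh1-HUMT and 15 fell and 1 rose in libraries labelled sh2-HUMT (25 and 19 adjusted over the list alone). Against the control mean, sh1-HUMT replicate 2 had a list median of -0.0858 for oxidative phosphorylation and -0.125 for ribosomal proteins (log2). Replicates 1 and 3 stood lower, at -0.205 and -0.217 and at -0.241 and -0.259. CYCS, cytochrome c, fell by 0.63 and 0.65, COX5A and COX7A2 by 0.31 and 0.26 and by 0.39 and 0.38, while NDUFV2 rose by 0.22 and 0.30 (log2). Camera called ribosomal proteins at adjusted p = 1.3e-12 and 8.0e-11, and oxidative phosphorylation at adjusted p = 7.5e-06 and 1.8e-04. All 4 calls were lost with an estimated correlation, at adjusted p = 0.202 and 0.29 with an estimated correlation for ribosomal proteins and adjusted p = 0.264 and 0.382 with an estimated correlation for oxidative phosphorylation. After the GC and length correction 21 and 17 ribosomal protein genes fell, with medians of -0.14 and -0.12, and 12 and 9 oxidative phosphorylation genes fell, with medians of -0.11 and -0.09 in place of -0.17 and -0.14. Camera's calls persisted at its preset correlation (adjusted p = 1.3e-07 and 2.5e-06 for ribosomal proteins, ranges over alternatives 4.1e-18 to 0.202 and 2.5e-14 to 0.29; adjusted p = 5.5e-04 and 0.0117 for oxidative phosphorylation, ranges 1.5e-08 to 0.264 and 2.5e-05 to 0.382). With that correction RPL7A changed by -0.14 and -0.11, COX5A by -0.18 and -0.14, COX7A2 by -0.24 and -0.22, NDUFV2 by 0.38 and 0.46, and RPL10A by -0.18 for sh1-HUMT. Across 11016 genes, which are not independent replicates, log2 change rose with transcript length (Spearman 0.332 and 0.242), and the median transcript of the ribosomal list measured 1985 bp against 3461 bp over all tested genes with a known length.

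**Figure D4:**
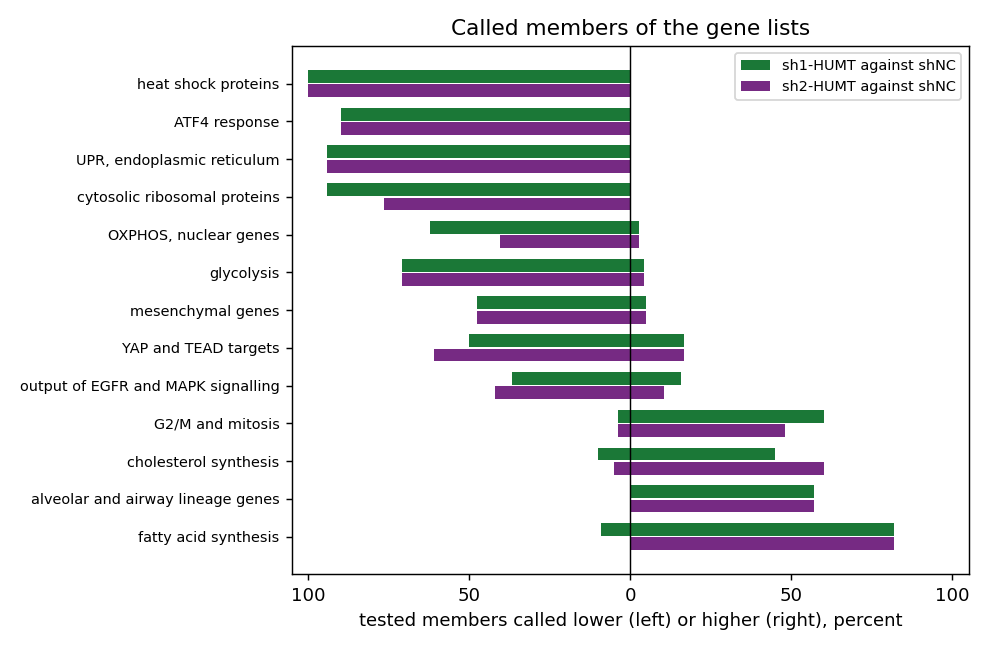
Percent of tested members of 13 gene lists called lower (left of 0) or higher (right of 0) in each group labelled as a knockdown against shNC, at an adjusted p below 0.05. All 12 heat shock genes were lower in both labelled groups, and 9 of 11 fatty acid synthesis genes were higher.

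Among genes of the cell cycle lists, more rose than fell, by small amounts. Of 25 genes of G2/M and mitosis, 15 rose and 1 fell in libraries labelled sh1-HUMT and 12 rose and 1 fell in libraries labelled sh2-HUMT (19 and 17 changed adjusted over the list alone). MKI67, a proliferation marker, rose from 262 ± 13.2 CPM to 354 ± 12.7 and 344 ± 1.39 CPM, beside BUB1 (0.39 and 0.36), TOP2A (0.25 and 0.18) and KIF20A (0.27 and 0.35). Camera called the list at adjusted p = 2.8e-05 and 3.1e-05, lost at adjusted p = 0.0802 and 0.0699 with an estimated correlation. With the GC and length correction, 20 and 19 of its genes rose. Of 24 G1/S and DNA replication genes, 8 rose in libraries labelled sh1-HUMT, and 7 rose and 1 fell in libraries labelled sh2-HUMT (9 and 8 adjusted over the list alone), MCM4 by 0.33 and 0.34 and PCNA by 0.14 and 0.13 (0.27 and 0.27 after the GC and length correction). That list was called for libraries labelled sh1-HUMT (adjusted p = 0.0352; adjusted p = 0.264 with an estimated correlation) and not for libraries labelled sh2-HUMT (adjusted p = 0.0867). The sh1-HUMT call was lost without shNC replicate 3 (adjusted p = 0.0598) or without sh1-HUMT replicate 2 (0.0933; range over alternatives 0.00535 to 0.264), and the sh2-HUMT list was called after the correction for GC content and length (adjusted p = 0.0284; range 0.0284 to 0.382). Of 22 DNA repair genes, 10 rose and 1 fell in libraries labelled sh1-HUMT and 5 rose and 2 fell in libraries labelled sh2-HUMT (13 and 7 adjusted over the list alone), among them MSH6 (0.18 and 0.14). DNA repair was called for libraries labelled sh1-HUMT (adjusted p = 0.0206; adjusted p = 0.118 with an estimated correlation) and not for libraries labelled sh2-HUMT (adjusted p = 0.155), and the first call was lost after the GC and length correction (adjusted p = 0.072; range 0.0106 to 0.118).

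Lists of p53 targets, apoptosis regulators and histones were not called. Of 20 p53 targets, 9 rose and 3 fell in libraries labelled sh1-HUMT and 7 rose and 4 fell in libraries labelled sh2-HUMT (12 and 13 adjusted over the list alone; camera, adjusted p = 0.174 and 0.592). GDF15, a secreted stress cytokine, fell from 623 ± 20.1 CPM to 340.3 ± 18.3 and 299 ± 8.11 CPM, while CCNG1 (0.29 and 0.33) and RRM2B (0.31 and 0.23) rose. CDKN1A, an inhibitor of cyclin-dependent kinases, had log2 differences of -0.03 (adjusted p = 0.54) and -0.12 (adjusted p = 0.0147). Its sh2-HUMT call was lost without shNC replicate 2 (adjusted p = 0.0654) or 3 (0.0568), or without sh2-HUMT replicate 2 (0.0642) or 3 (0.0596; range over alternatives 0.00188 to 0.0654). Of 18 genes of the BCL2 family and inhibitors of apoptosis, 4 rose and 6 fell in libraries labelled sh1-HUMT and 5 rose and 5 fell in libraries labelled sh2-HUMT (11 adjusted over the list alone in each; camera, adjusted p = 0.326 and 0.341). PMAIP1, a proapoptotic member, fell by 0.78 and 0.84, MCL1 by 0.22 and 0.20 and BCL2L1 by 0.16 and 0.24 (log2). Of 11 replication-dependent histones, a family whose members share sequence, 1 passed the test in libraries labelled sh1-HUMT and 2 in libraries labelled sh2-HUMT (1 and 2 adjusted over the list alone; camera, adjusted p = 0.846 and 0.592).

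Among output genes of EGFR and MAPK signalling more fell than rose, and EGFR itself did not pass the test. Of 19 output genes, 7 fell and 3 rose in libraries labelled sh1-HUMT and 8 fell and 2 rose in libraries labelled sh2-HUMT (11 adjusted over the list alone in each), with medians of -0.06 and -0.11. The GC and length correction gave 9 lower genes in each comparison and medians of -0.13 and -0.14, and without shNC replicate 3 the sh2-HUMT median was -0.06. FOSL1, an AP-1 subunit, fell from 74.8 ± 3.67 CPM to 27.0 ± 1.07 and 25.7 ± 0.733 CPM, beside the phosphatase DUSP5 (-0.90 and -0.83) and MYC (-0.62 and -0.62). The list was called (adjusted p = 0.0168 and 0.00111), and the calls were lost at adjusted p = 0.118 and 0.0675 with an estimated correlation. EGR1, described above among stress-induced genes, belongs to this list and changed by -5.71 and -6.04. It pulled the list means to -0.47 and -0.52, well below the medians, and the list was not tested without it. Of 26 receptor tyrosine kinases and EGFR ligands, 8 rose in each comparison and 5 and 7 fell (15 adjusted over the list alone in each; camera, adjusted p = 0.892 and 0.983). ERBB3, a partner receptor of EGFR, rose from 11.9 ± 1.46 CPM to 24.9 ± 1.45 and 25.6 ± 1.34 CPM, while the ligands AREG (-0.65 and -0.76), EREG (-0.53 and -0.72) and NRG1 (-0.45 and -0.55) fell. EGFR stood at 257 ± 8.74, 255 ± 8.88 and 250.3 ± 0.468 CPM in shNC, sh1-HUMT and sh2-HUMT (adjusted p = 0.875 and 0.433). MET had log2 differences of -0.05 (adjusted p = 0.148) and -0.12 (adjusted p = 0.00417), and AXL of 0.04 and -0.04 (adjusted p = 0.273 and 0.266). After the GC and length correction EGFR was called lower in both (-0.13 and -0.13), MET in the sh1-HUMT comparison (-0.11) and AXL in the sh2-HUMT comparison (-0.10).

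Among mesenchymal genes and among targets of YAP and TEAD, more fell than rose. Of 21 mesenchymal genes, 10 fell and 1 rose in each comparison (12 and 11 adjusted over the list alone; camera, adjusted p = 0.00128 and 0.00169; adjusted p = 0.118 and 0.113 with an estimated correlation). TGFBI, an extracellular matrix protein induced by TGF-beta, fell from 907 ± 18.4 CPM to 592 ± 3.24 and 578 ± 4.35 CPM, beside LOXL2 (-0.44 and -0.37), MMP2 (-1.27 and -0.93) and vimentin, VIM (-0.24 and -0.17). Of 15 epithelial genes, 2 rose and 5 fell in libraries labelled sh1-HUMT and 3 rose and 4 fell in libraries labelled sh2-HUMT (7 adjusted over the list alone in each), and the list was not called (adjusted p = 0.528 and 0.758). E-cadherin, CDH1, rose by 0.33 and 0.32 and ELF3 by 0.22 and 0.25, while the keratins KRT19 and KRT7 fell by 0.70 and 0.56 and by 0.55 and 0.58 (log2). Of 18 YAP and TEAD targets, 9 and 11 fell and 3 rose in each comparison (14 adjusted over the list alone in each), CYR61 from 65.6 ± 1.37 CPM to 29.2 ± 1.08 and 26.6 ± 1.04 CPM, GADD45B by 0.89 and 1.05 and NUAK2 by 0.58 and 0.70; CRIM1 rose by 0.50 and 0.41. Camera called it at adjusted p = 0.0373 and 0.00282, lost at adjusted p = 0.202 and 0.103 with an estimated correlation, and for libraries labelled sh1-HUMT also without sh1-HUMT replicate 2 (adjusted p = 0.0933; range over alternatives 0.00269 to 0.202).

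Inflammatory genes moved both ways. Of 21 NF-kB targets and cytokines, 10 fell in each comparison and 4 and 5 rose (15 adjusted over the list alone in each). CXCL8, the neutrophil attractant interleukin 8, fell from 144 ± 5.31 CPM to 39.4 ± 1.92 and 42.5 ± 0.317 CPM and TNFAIP3 by 0.99 and 1.01, while SOD2 (0.47 and 0.58) and TNFAIP2 (0.35 and 0.46) rose. The list was called for libraries labelled sh1-HUMT (adjusted p = 0.0454; adjusted p = 0.339 with an estimated correlation) and not for libraries labelled sh2-HUMT (adjusted p = 0.0852). The call was lost without shNC replicate 1 (adjusted p = 0.0891), without sh1-HUMT replicate 1 (0.084), with the replicate number as a block (0.059) and after the GC and length correction (0.202; range over alternatives 0.0305 to 0.339). Of 23 interferon-stimulated genes, 3 and 4 rose and 1 fell (4 and 5 adjusted over the list alone; camera, adjusted p = 0.706 and 0.702), with OAS1 at 0.31 and 0.44 and OAS3 at 0.32 and 0.31. IFIT1 had log2 differences of 0.17 (adjusted p = 0.22) and 0.37 (adjusted p = 0.0125); the sh2-HUMT call was lost without sh2-HUMT replicate 3 (adjusted p = 0.0516; range 0.00846 to 0.0516).

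Of 17 drug transporters and detoxification genes, 4 rose and 6 fell in libraries labelled sh1-HUMT and 6 rose and 4 fell in libraries labelled sh2-HUMT (10 adjusted over the list alone in each; camera, adjusted p = 0.846 and 0.592). The efflux pumps ABCC3 and ABCC4 rose by 0.23 and 0.22 and by 0.46 and 0.41, and the lipid transporter ABCA3 by 0.27 and 0.29 (after the GC and length correction ABCC3 by 0.15 and 0.12 and ABCA3 by 0.17 and 0.15), while the aldehyde dehydrogenase ALDH3A1 fell from 3798 ± 51.1 CPM to 2837 ± 84.5 and 2869 ± 18.3 CPM. ABCB1, the P-glycoprotein pump, was scarce, at 0.452, 0.164 and 0.479 CPM, with log2 changes of -1.43 (adjusted p = 0.0475) and 0.08 (adjusted p = 0.914); the first call was lost on leaving out any 1 of the 9 libraries (adjusted p = 0.0543 to 0.167), with no filter on low counts (0.0816) and with the replicate number as a block (0.0842; range over all alternatives 0.047 to 0.167). FOXK1, a transcription factor of glycolysis genes, changed by 0.36 (adjusted p = 0.00387) and 0.23 (adjusted p = 0.0366). After the GC and length correction both calls were lost (log2 0.21 and 0.06, adjusted p = 0.0538 and 0.568; ranges 3.1e-07 to 0.0538 and 0.00219 to 0.568). The sh2-HUMT call for FOXK1 was lost without shNC replicate 1 (0.073) or 3 (0.069), without sh1-HUMT replicate 2 (0.0645) and without sh2-HUMT replicate 1 (0.0792) or 3 (0.123), and with the replicate number as a block (0.0806) or no filter on low counts (0.052).

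Markers of other cell types were not called as lists. Of 9 fibroblast genes, 2 rose and 1 fell in each comparison (3 adjusted over the list alone in each; camera, adjusted p = 0.88 and 0.641), with ACTA2 at 0.32 and 0.36 and COL5A1 at -0.48 and -0.37. The 6 leukocyte genes had medians of -0.01 and 0.24 (0.10 and 0.28 after the GC and length correction; camera, adjusted p = 0.836 and 0.641), and the 3 endothelial genes medians of -0.18 and -0.08 (-0.14 and -0.14 after that correction; adjusted p = 0.92 and 0.758; 2 and 1 changed over all genes, and 2 and 1 adjusted over the list alone). Median, mean and test differed in sign for receptor tyrosine kinases, epithelial genes, interferon-stimulated genes and drug transporters in both comparisons, for leukocyte genes in libraries labelled sh1-HUMT, and for fibroblast and endothelial genes in libraries labelled sh2-HUMT. In all, camera called 17 of 29 lists for libraries labelled sh1-HUMT and 13 for libraries labelled sh2-HUMT, and 5 and 6 with an estimated correlation. Splits of the same libraries with mixed labels also gave 4 to 9 called lists at the preset correlation.

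Between the groups labelled with either hairpin, the number of genes that differed depended on the test and on single libraries. ATF4 response genes were lower in the libraries labelled sh2-HUMT than in those labelled sh1-HUMT: 8 of 20 fell (16 adjusted over the list alone), with a median log2 difference of -0.20. ASNS, the asparagine synthetase, stood at 76.4 ± 5.35 against 95.8 ± 1.71 CPM (-0.33), and GARS (-0.23), TRIB3 (-0.23) and STC2 (-0.20) went the same way. BCAT1, a transaminase of branched-chain amino acids, changed by -0.66 and ADM2, a hormone gene related to ADM, by -0.88, while HSPA1A was higher, at 74.9 ± 1.02 against 57.9 ± 2.63 CPM (0.37). In edgeR 53 of 18540 genes differed, 20 higher and 33 lower in libraries labelled sh2-HUMT, and after the GC and length correction 51 did, 7 higher and 44 lower. Across 11016 genes, the log2 difference between these groups rose with GC content (Spearman 0.353) and fell with transcript length (Spearman -0.226). Some of the 53 calls may follow these trends. DESeq2 called 366, 172 higher and 194 lower, whereas edgeR called 29 with the replicate number as a block and 35 with only the 2 groups compared. The count moved with single libraries: 1 gene, HSPA1A, without sh2-HUMT replicate 1, 6 without replicate 2 and 9 without replicate 3, 16, 155 and 27 without sh1-HUMT replicates 1, 2 and 3, and 24 without shNC replicate 1. ASNS, at adjusted p = 0.0486, lost its call on leaving out any library but shNC replicate 3 (0.0702 to 0.175), with upper-quartile normalization (0.0546), with the replicate number as a block (0.0725) and after the GC and length correction (0.0642; range over alternatives 7.9e-07 to 0.175). GARS lost its call without sh2-HUMT replicate 1 (0.0667; range 2.6e-13 to 0.0667), and STC2 without sh1-HUMT replicate 1 (0.0559) or sh2-HUMT replicates 1 (0.0667), 2 (0.0805) or 3 (0.0733; range 3.3e-06 to 0.0805). TRIB3 lost its call on leaving out any library but sh1-HUMT replicate 2 (0.0510 to 0.165) and with only the 2 groups compared (0.0829; range 2.8e-06 to 0.165). BCAT1 lost its call without sh2-HUMT replicates 1 (0.0667) or 2 (0.0623; range 0.00288 to 0.0667), and ADM2 lost its own without shNC replicate 1 (0.0542), sh1-HUMT replicates 1 (0.0573) or 3 (0.0865) or sh2-HUMT replicates 1 (0.133) or 3 (0.121) and with only the 2 groups compared (0.0714; range 0.0135 to 0.133).

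Camera called 6 lists between these groups. ATF4 response (adjusted p = 2.1e-20) held with an estimated correlation (adjusted p = 0.018 with an estimated correlation). The others were heat shock, higher in libraries labelled sh2-HUMT (2 of 12 genes rose, 6 changed adjusted over the list alone; adjusted p = 0.00219), and YAP and TEAD targets (0.00268), p53 targets (0.0226), EGFR and MAPK output (0.0357) and DNA repair (0.038), all lower, with 5, 2, 1 and 1 genes adjusted over the list alone. These 5 were lost, each at adjusted p = 0.205 with an estimated correlation. Glycolysis was not called (adjusted p = 0.392), nor were hypoxia response (0.448), G1/S and DNA replication (0.678) or NF-kB targets (0.359). Median, mean and test differed in sign for lists that were not called: NRF2 targets, tricarboxylic acid cycle, unfolded protein response, G1/S, G2/M, mesenchymal genes, NF-kB targets and leukocyte genes. The number of lists was 10 without sh1-HUMT replicate 2, which lay apart from the other libraries on the second principal component (37.2 against -27.4 to 18.7), and 3 without sh2-HUMT replicate 1.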

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

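The tests of the heat shock and LINC00857 patterns were chosen only after the results they measure had been seen; those of the ribosomal, respiratory chain and glycolysis lists were set before they were run but after the length trend and corrected list values had been seen, and the splits of the samples were planned.

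Between the groups labelled sh2-HUMT and sh1-HUMT, 53 genes differed by edgeR's test of the difference itself. Over 11016 genes this difference rose with GC content (Spearman 0.353), so some of these calls may follow GC content. The ATF4 response list lay lower in libraries labelled sh2-HUMT (median -0.20, log2), as did ASNS (-0.33), TRIB3 (-0.23), GARS (-0.23), STC2 (-0.20) and BCAT1 (-0.66). ADM2 (-0.88), FAM129A (-0.39), LOC105371074 (-0.36), JUN (-0.30), PPP1R15A (-0.19) and the EGFR ligand EREG (-0.19) were lower too. Higher in libraries labelled sh2-HUMT were HSPA1A (0.37), HSPA1B (0.39), KIFC2 (0.30), RCN3 (0.45), USP7 (0.68) and RBM14-RBM4 (0.81), a readthrough entry whose reads overlap both parent genes. Of these 17 genes, 16 lost their call without sh2-HUMT replicate 1 (adjusted p = 0.0667 to 0.196; range over alternatives 2.6e-13 to 0.196), HSPA1A being the exception (0.0258). Without sh2-HUMT replicate 1 a single call was left among all genes, without replicates 2 and 3 there were 6 and 9, without sh1-HUMT replicates 1, 2 and 3 there were 16, 155 and 27, and without shNC replicate 1 there were 24. DESeq2 called 366.

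Chosen after their values were seen, 2 further genes differed at least 2-fold between these groups. LOC100996447 had 25, 25 and 12 counts in shNC, 0 in each library labelled sh1-HUMT and 22, 14 and 23 in those labelled sh2-HUMT. The entry BGIG9606_68069 had 21, 9 and 26, then 0 in each, then 14, 17 and 13 counts. The first lost its call without sh2-HUMT replicates 1 (adjusted p = 0.0667), 2 (0.0510) or 3 (0.0605; range over alternatives 0.00288 to 0.0667). The other lost its call without shNC replicate 1 (0.0689), sh1-HUMT replicates 1 (0.0873) or 3 (0.0721) or sh2-HUMT replicates 1 (0.105), 2 (0.101) or 3 (0.0811), and with the replicate block (0.0872; range 0.00726 to 0.105). No fold is given, as a fitted value against 0 depends on the prior count.

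For the counts of genes and lists, 10 splits of 6 libraries are too few for a share under 0.05, and the real split was the 1 as large in each case. The real counts and the highest of the other splits were 5923 and 0 genes for sh1-HUMT against shNC, 6019 and 1 for sh2-HUMT against shNC, 53 and 3 between the hairpin groups, and 17 and 9 lists and 13 and 9 lists for both comparisons with shNC. Every other split gave list calls at camera's preset correlation, 6 to 9 for sh1-HUMT and 4 to 9 for sh2-HUMT. A camera call at that setting is therefore weak evidence by itself. These splits keep part of the group difference, so their list calls are not all false calls. For the 4654 genes changed the same way in both, 1 of 60 assignments drawn from 840 gave as many, and that was the real assignment. The highest other, 4482, kept the 3 shNC libraries together and exchanged libraries between the hairpin groups. With the shNC libraries apart the highest was 1. A random grouping of the libraries is thus an unlikely source of the count. The count depended on keeping the shNC libraries together, so a difference of the control cultures that arose by chance is not excluded.

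The heat shock list was high in all 3 libraries labelled shNC: the lowest control lay 0.951 above the highest other library in the list's median (log2), more than the 0.0370 range of the controls, which argues against a single stressed control library. After the GC and length correction the median stayed at -0.94 or lower, which argues against a length or GC trend as the whole cause. For the counted LINC00857 gene, the lower 95% bound of the log2 change was -0.24, which argues against a loss of 50% of that gene's counts. It does not bear on a HUMT transcript outside the counted gene model, which stays open as a target of the hairpins. Handling of the control cultures that differed from the others (time before lysis, temperature, fresh medium) would give the same gap of 0.951 and cannot be told apart from the groups, because the labels give the same protocols for every sample. An action of either hairpin that leaves the counted level as it was stays open and was not tested.

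LINC00857 was not called lower in libraries labelled as its knockdown. Too few counts to see a loss of 50% are excluded by the lower bound of -0.24. The lowest of the 9 libraries stood at 84.2% of the highest. An exchange of libraries between groups therefore did not hide a loss of 50% of the counted gene. If the hairpins left the level of that gene as it was, this value cannot show whether libraries were exchanged. Whether the columns hold A549 cells, as their headers say, cannot be told apart from what the labels say with no reference library of either line: CDKN2A reached at most 3.16 counts while its neighbour MTAP had 2336 to 2722. AKR1B10 (31539 to 38383 counts), ALDH1A1 (81127 to 85784) and NQO1 (36129 to 39451) ranked 33, 8 and 30 among 27059 genes by mean count. No biological explanation was tested, and a HUMT isoform outside the counted gene model stays open.

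Small falls of ribosomal, respiratory chain and glycolysis genes were set against random lists matched on GC content, length and expression. Glycolysis lay at the 1.09 percentile or lower in both comparisons, with medians of -0.15 and -0.15 against -0.05 and -0.05 for the typical matched list. Matched genes thus fell less than the list did. The random lists were drawn gene by gene, so they lack the correlation between members of a list (estimated at 0.15 for glycolysis). The list was also picked for its fall, and both comparisons share their controls. The percentile therefore cannot decide whether a trend was the whole cause. Ribosomal proteins lay at the 0.920 and 2.73 percentiles and the respiratory chain at 1.14 and 6.70, so with one comparison on either side of the 2.5 percentile a trend with length or GC content cannot be told apart from a change of these lists. All 6 libraries lay below all 3 controls in each list's median (exact two-sided permutation p = 0.0119, the smallest that 84 splits can give), but the lists were picked for their fall in these libraries, so shifts of a list from library to library cannot be told apart from the groups by that test. An effect of the hairpins, the groups of the design, stays open as untested beyond these comparisons.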

How the results depend on the processing

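The GC and length correction, the removal of the 2 most abundant entries and every value for lists between the hairpin groups were chosen after seeing the data; the other alternatives were planned. A pseudocount and a minimum mean set for normalized values were not run, as they have no place in a count test. No called result reversed under any alternative. With a log2 fold minimum of 1, the counts fell to 361 (sh1-HUMT), 372 (sh2-HUMT), 230 (both the same way) and 2 (sh2-HUMT against sh1-HUMT), by construction. With an estimated correlation, 5, 6 and 1 lists remained called for sh1-HUMT, sh2-HUMT and between the hairpin groups. The 53 genes between the hairpin groups became 35 with only the 2 groups compared, 366 with DESeq2 and 1 to 155 on leaving out a library; the cause was not tested. Their 6 lists became 10 without sh1-HUMT replicate 2 and 3 without sh2-HUMT replicate 1.

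The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.025 to 0.050. The replicate block gave 5717, 5778, 4491 and 29 genes and 16, 13 and 4 lists in the same order of comparisons. Leaving out a library gave 4776 to 5740 genes for sh1-HUMT, 4881 to 6240 for sh2-HUMT and 3844 to 4549 for both, with 15 to 17 and 13 to 14 lists. On leaving out a library LINC00857 lay between 0.00 and 0.11, between -0.10 and 0.01, and between -0.15 and -0.07 (log2), and after the GC and length correction at 0.13, 0.02 and -0.10; the sign for sh2-HUMT turned with that correction and without shNC replicate 2. It was not called under any alternative that gave an adjusted p; DESeq2 gave none between the hairpin groups. The GC and length correction gave 5605, 5798, 4456 and 51 genes, of which 4788, 4916, 3734 and 34 were the same genes, and moved the higher share between the hairpin groups from 37.7% to 13.7%. In counts simulated with a length trend of 0.2 (log2 per SD) it lowered false calls from 3790 and 3789 to 6 and 15, and recovery of 2-fold and 4-fold changes from 92.9% and 91.8% to 81.6% in both. Small changes called without it may therefore include length trends. The drop in recovery need not be a loss of power. Counts simulated without a trend gave 66.0% at 2-fold and 97.9% at 4-fold in both comparisons. The many false calls without the correction also made the adjusted threshold looser. Of 145 named genes, 17 lost a call against shNC under some alternative other than the fold minimum, 15 of them on leaving out a library.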

Other observations

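All 4 lists and all tests here were chosen after the data were seen. Of the genes tested, 9 of 24 immediate early genes, 3 of 20 synthetases and 5 of 10 mucins were in lists or among genes already described. The other immediate early genes and synthetases include genes called before the lists were chosen, so both have counts and medians without a list test. Of 24 immediate early genes tested, which growth factors and stress induce within minutes, 20 were lower and 3 higher than shNC in both groups labelled as knockdowns (24 changed adjusted over the list alone), with median log2 changes of -1.03 and -0.99. Of the 15 not yet described, 12 were lower and 2 higher in each comparison (15 adjusted over the list alone; medians -0.84 and -0.83). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 were lower and 1 higher in libraries labelled sh1-HUMT and 16 were lower in those labelled sh2-HUMT (17 and 18 adjusted over the list alone; medians -0.33 and -0.50). Of the 17 not in the ATF4 response list, 11 and 13 were lower (14 and 15 changed adjusted over the list alone; medians -0.32 and -0.44). Between the hairpin groups 7 of the 20 were lower in libraries labelled sh2-HUMT (13 adjusted over the list alone), among them IARS, TARS and AARS. IARS, TARS and AARS lost their calls without sh2-HUMT replicate 1 (adjusted p = 0.0521, 0.0667 and 0.0733), TARS also without sh2-HUMT replicate 3 (0.0667), and AARS also without sh1-HUMT replicate 1 (0.0533) and sh2-HUMT replicates 2 (0.0755) and 3 (0.0605). Their ranges over alternatives were 1.9e-16 to 0.0521, 2.2e-09 to 0.0667 and 4.5e-11 to 0.0755.

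Of 10 mucins tested, MUC1, MUC2, MUC5AC, MUC5B and MUC16 are those already described. The other 5 had median log2 changes of 0.27 and 0.41 and were not called as a list at camera's preset correlation (adjusted p = 0.341 and 0.0751) or with an estimated correlation (adjusted p = 0.369 and 0.119). Of 31 proteasome subunits, 16 and 15 were lower and 1 higher (19 adjusted over the list alone in each), with medians of -0.12 and -0.11. The list was called at camera's preset correlation (adjusted p = 1.6e-05 and 4.6e-06), and the calls were lost at adjusted p = 0.0844 and 0.0703 with an estimated correlation. The proteasome list was chosen after the values of its members could be seen, so its list test gives no separate support. The GC and length correction gave 5 and 7 lower proteasome subunits and medians of -0.07 and -0.04.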
